A study of Arabidopsis thaliana with 40 samples.

How the data were processed

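Acetylation of histone H3 at lysines 9 and 14 (H3K9/14ac), a mark found at the promoters and gene bodies of active genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq). The material was 7-day-old seedlings of Arabidopsis thaliana, ecotype Col-0, grown in shaken liquid culture under short days, per the labels' protocols. Seedlings received water, 250 µM S-nitrosoglutathione (GSNO, a donor of nitric oxide), 250 µM glutathione (GSH, the same tripeptide without the nitroso group), 250 µM GSNO together with 500 µM cPTIO (a scavenger of nitric oxide), or 5 µM trichostatin A (TSA, an inhibitor of histone deacetylases). Each treatment lasted 3 h or 16 h. Per the labels there were 2 biological replicates of each treatment and time, each with a ChIP and an input library, which gives 40 samples, 20 of them ChIP and 20 input. Groups were taken from the sample titles. The input libraries were not analysed here as files of their own.

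The authors deposited a peak list for each ChIP library and 7 tables of differential binding, which cover each treatment against water at 3 h, and GSNO, GSH and GSNO with cPTIO against water at 16 h. TSA at 16 h was analysed here as peak lists alone. DiffBind and edgeR are named, without versions, per the submitters' processing notes, which also name the genome builds TAIR10 and TAIR9. The aligner, the peak caller and the read filters are not given in the sources used here. Each of the 7 tables lists the same 13362 regions with coordinates, which are printed here as the tables give them. The values per region are the log2 mean of normalised reads in each group and the log2 fold of treatment over water, both as the authors deposited them. The tables also hold a p-value and a false discovery rate (FDR) per region from the authors' deposited test. These tables carry group means, with no column per library. The design written before the data were examined named the authors' deposited fold and FDR as the test for that case, and a region was called at an FDR under 0.05.

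The group means proved to be sums of whole reads times 1 factor per library, so the reads of each library were recovered from them. The values of 100% of regions came out whole within a tolerance of 1e-08. The recovery was tested on simulated pairs of 3000 regions, where 100% of values were right. The water libraries of 3 h had the same reads in each table of that time. In all 17 libraries were recovered, 2 for each of 5 groups of 3 h and 3 groups of 16 h, and a single water library of 16 h, the same in each of the 3 tables of that time. Recovered libraries carry no replicate number and are called a and b, a being the shallower. The lowest value in any library was 1 read. Whether input reads were subtracted or values of 0 replaced is not given in the sources used here, so 1 read was treated as the floor, and log2 folds against groups at the floor depend on it. For most such regions named here a bound against 3 reads per library, or the range of the bounds, is also given. Reads in the regions ranged from 1590342 (water, 16 h) to 4053207 (GSNO, 3 h, library b), with medians per region from 104 to 275. Trimmed mean (TMM) factors computed from the recovered reads differed from those of the tables by at most 1.39%.

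Recovered reads were scaled by TMM factors (trims of 0.3 for folds and 0.05 for levels), moved to log2 with a pseudocount of 1, and tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided, Benjamini-Hochberg adjustment over 13362 regions). This fold is on the log2(value + 1) scale and understates changes of low regions. For treatment against water, the limma test was added after the tables had been seen. For GSNO against GSH, GSNO against GSNO with cPTIO, and the difference of a response between 3 h and 16 h, it was the planned test, with the water libraries in the fit. The lone water library of 16 h was assumed to vary like the other groups. P-values measure the spread between 2 cultures per group. With no change, an unadjusted p under 0.05 would be found at about 5% of the 13362 regions. In simulated reads with 200 changed regions among 13362, 4-fold changes were recovered at 100% in each comparison simulated, and 2-fold changes at 36% (GSNO with cPTIO, 16 h) to 92% (GSH, 3 h). With TSA at 3 h, 87% of the simulated 2-fold changes were recovered. These reads were drawn once per comparison, so the shares recovered and the shares of false calls that follow are rough. For TSA, 12 of 199 calls were false, a share that cannot be told apart from 5%. Of the simulated calls, 13.3% were false for GSH at 16 h, 9.84% for GSNO at 16 h, 8.84% for GSNO, 7.69% for GSH and 6.03% for TSA at 3 h, above the nominal 5%, and at most 2.86% in the other comparisons. With no region changed, 20 simulations per comparison called at most 7 regions for GSH at 16 h, 3 for GSNO with cPTIO at 16 h and 1 elsewhere. Both kinds of simulation gave all regions of a comparison the same dispersion and drew the libraries independently. They do not cover regions that vary more between libraries, for which the share recovered is not known.

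Regions were linked to protein-coding genes of the TAIR10.1 annotation, which served for names and neighbourhood only. As no strand was given in the annotation used here, a region was linked to the gene it overlaps, or otherwise to the nearest gene within 1 kb, in place of the planned rule on gene starts. Of the regions, 97.6% overlapped a gene, 193 were linked within 1000 bp and 125 had no gene. Among those that overlapped genes, 782 overlapped 2 genes and 23 overlapped 3, and their signal cannot be assigned to 1 of them. Midpoints of 95.1% of regions lay within 1 kb of a gene end, against 58.1% for randomly placed intervals. When the regions were shifted, the share of midpoints within 500 bp of a gene end fell from 55.5% to between 40.7% and 51.9%.

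Before the data were examined, 12 gene lists with 271 genes were written down, and all 271 codes were found in the annotation: photosynthesis; circadian clock and light; immune signalling and salicylic acid; jasmonate; ethylene, touch and calcium; abscisic acid, cold and drought; oxidative stress, detoxification and heat shock; nitric oxide, nitrate and glutathione; histone acetyltransferases and deacetylases; reference genes; and markers of root and of shoot tissue. The 10 lists with at least 5 regions were tested with limma's camera at a preset correlation of 0.01, adjusted over 150 tests (10 lists in 15 comparisons), then with the correlation estimated and with fry. The genes named in the text follow a rule of the same date. For each treatment against water they are up to 10 regions with the largest rise and 10 with the largest fall among called regions in which the treated libraries lie beyond the water libraries, or the 5 with the smallest p where fewer than 3 pass. A rise with a treated library at 1 read, or a fall with a water library at 1 read, was not counted as beyond. Up to 4 members of each list with the smallest p were added. Regions outside this rule are said to be so, and not every region that it names is reported here. Peaks were compared by overlap of at least 1 bp and by the genes they overlap. Floors of 3 reads cover counting error only.

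Alternatives were a pseudocount of 8, a filter on mean values under 20, equal medians of libraries, limma without trend, adjusted p under 0.1, leaving out each library, other overlaps and stricter peaks. Tests of groups of 2 by permutation cannot go below p = 0.333, so none was used for calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.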

Results

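The series asks which H3K9/14ac sites in Arabidopsis seedlings respond to nitric oxide. It sets the donor GSNO beside GSH, which lacks the nitroso group, beside GSNO with the scavenger cPTIO, and beside TSA, which blocks histone deacetylases. Each treatment and time had 2 ChIP libraries. The 17 libraries behind the differential tables held from 1590342 reads in the 13362 regions (water, 16 h) to 4053207 (GSNO, 3 h, library b). In the first water library of 3 h, 96.5% of peak midpoints lay in genes, against 54.2% for random placement, and in water replicate 2 of 16 h 37.6%, against 53.9%. Each library of 3 h had between 7885 peaks (GSNO, replicate 2) and 13882 peaks (water, replicate 1), and the mean with TSA was 12396 against 11509 in water. An exact two-sided permutation test of these means gave p = 1 with 2 libraries per group, and the smallest p that such a test allows is 0.333. At 16 h the water lists held 6838 and 1200 peaks, and the TSA lists 14758 and 385. The list of water replicate 2 at 16 h had 83 peaks on the mitochondrial and 73 on the plastid genome. Only 0.766% of its peaks overlapped those of replicate 1, while the median over the 10 groups was 96.0% of the smaller list. Genes with a peak in both replicates numbered 8842 in water and 10489 with TSA at 3 h, but 122 in water and 315 with TSA at 16 h, so sets of genes with peaks at 16 h were not compared.

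**Figure D1:**
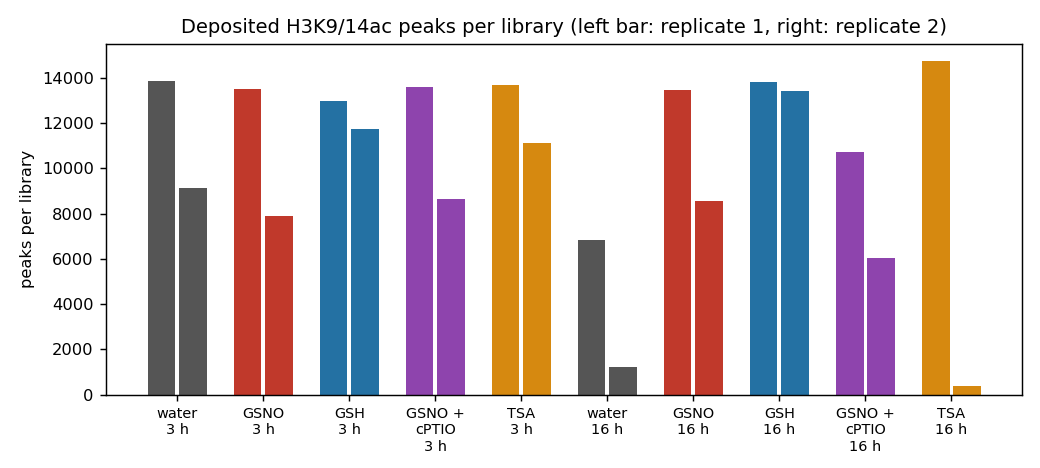
Number of deposited H3K9/14ac peaks (y axis) in each of the 20 ChIP libraries, grouped on the x axis by treatment and time, with replicate 1 as the left and replicate 2 as the right bar of each pair. The second libraries of water and TSA at 16 h hold 1200 and 385 peaks.

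After 3 h with TSA the largest rises in acetylation lay at AT5G06980, at LHB1B2 and LHCA1, which encode antenna proteins of the photosystems, and at GI (GIGANTEA) and PRR9, components of the circadian clock. Their log2 folds in the authors' deposited table were 7.47, 7.36, 6.19, 7.25 and 5.93. Losses were largest at PPC2, a phosphoenolpyruvate carboxylase, and beside XTH18, an enzyme of cell wall remodelling, with folds of -3.99 and -3.16 in the authors' deposited table. The expansin gene EXPA6 also fell, with a fold of -2.26 there. In total 1425 regions were higher and 1353 lower at an FDR under 0.05 in the authors' deposited table.

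At LHB1B2 (AT2G34420; chromosome 2, 14522781 to 14523510) the TSA libraries had 159 and 165 reads and each water library 1 read, at least 54.7-fold higher against a floor of 3 reads per water library. At GI (AT1G22770; chromosome 1, 8061885 to 8062650) 175 and 125 reads stood against 1 and 1, at least 50.7-fold higher. The bounds were at least 59.2-fold higher for AT5G06980 and at least 20.3-fold higher for PRR9. LHCA1 (AT3G54890; chromosome 3, 20339859 to 20340964) had 217 and 234 reads with TSA against 1 and 7 in water, and limma gave a log2 fold of 5.96 ± 1.58 (SE; adjusted p = 0.00722). The other large rises were at AT3G53830, LHCB3, PIF4, a transcription factor of light and temperature responses, and STO, a B-box protein of light signalling, with folds of 4.89, 4.77, 4.65 and 4.27 in the authors' deposited table. A region at MRE11, a DNA repair nuclease whose gene lies next to LHCB3, had a fold of 4.79 in the authors' deposited table, with 7 and 48 reads against 1 and 1, at least 9.20-fold higher. The STO region overlaps a second gene.

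PPC2 (AT2G42600; chromosome 2, 17734424 to 17735143) had 1 and 10 reads with TSA against 75 and 111 in water. EXPA6 fell by 2.24 ± 0.36 on the log2 scale (SE; limma adjusted p = 7.73e-05), with 36 and 46 reads against 150 and 288. GATA1, a GATA-type transcription factor, fell by 1.95 ± 0.30 (adjusted p = 3.91e-05), and AT5G50110 by 2.32 ± 0.44 (adjusted p = 0.000467), both on the log2 scale in limma. The region beside ZAT10, a zinc finger factor of stress responses, had a fold of -2.20 in the authors' deposited table, and a second region at ZAT10 one of -0.90. Further large losses in the authors' deposited table were at AT1G69550 (-2.48), AT4G20300 (-2.03), AT3G11591 (-1.89) and a stretch of chromosome 4 without a linked gene, 11374349 to 11375003 (-2.50).

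Among the lists, photosynthesis had 13 higher and 1 lower of 25 regions with TSA in the authors' deposited table, and the same 13 and 1 adjusted over the list alone. LHCB2.1 and LHCB6, further antenna genes, had folds of 3.05 and 2.04 in the authors' deposited table beside LHCA1 and LHCB3. In limma, LHCB6 rose by 2.03 ± 0.24 (SE; adjusted p = 4.42e-06). Camera gave adjusted p = 0.00258 for a rise of this list, and adjusted p = 0.949 with an estimated correlation. Circadian clock and light had 6 higher and 1 lower of 17 regions in the authors' deposited table (7 and 2 adjusted over the list alone), PRR7 with a fold of 3.30 among them; camera gave adjusted p = 0.689, and adjusted p = 0.949 with an estimated correlation. Immune signalling and salicylic acid had 8 lower and 1 higher of 32 in the authors' deposited table, and as many adjusted over the list alone. Folds there were -0.96 at the kinase gene MPK3, -1.18 at PAD4, a lipase-like regulator of defence, -0.87 at the syntaxin gene SYP122 and -0.86 at the NADPH oxidase gene RBOHD, each from the authors' deposited table. Camera gave adjusted p = 0.00258 for a fall, and adjusted p = 0.949 with an estimated correlation. The median fold in the authors' deposited table was -0.39 for this list, -0.39 for ethylene, touch and calcium and -0.27 for reference genes. The other lists had medians from -0.09 (jasmonate) to 0.62 (photosynthesis). No list was set against regions of the same level, so the fall is not shown to be particular to immune genes.

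Ethylene, touch and calcium genes had 3 lower and 0 higher of 15 regions in the authors' deposited table (5 lower adjusted over the list alone), TCH2 (-1.01), ERF4 (-0.90) and ERF5 (-0.64). Camera gave adjusted p = 0.0609 for this list. Abscisic acid, cold and drought had 2 higher and 4 lower of 17, with ABF3 at 0.90 and RD26 at -0.81 in the authors' deposited table. Jasmonate had 3 higher and 4 lower of 21 (5 lower adjusted over the list alone), with ORA59 at 1.26, JAR1, which conjugates jasmonate to isoleucine, at 1.06, and JAZ2 at -0.72 in the authors' deposited table. Oxidative stress, detoxification and heat shock had 2 higher and 3 lower of 17, including CAT2 at 0.93 and ZAT12 at -1.32 in the authors' deposited table. Nitric oxide, nitrate and glutathione had 1 higher, GR2 at 0.63, and 2 lower of 17, NIA2 at -0.90 and NTRB at -0.66, in the authors' deposited table. Of 22 regions at histone acetyltransferases and deacetylases, 2 were higher (HDA15 at 0.91 and HD2B at 0.80) and 2 lower (HAM2 at -0.95 and HAF2 at -1.09) in the authors' deposited table. Of 14 regions at reference genes 1 was lower, UBQ10, at -0.85 in the authors' deposited table. Neither of the 2 root marker regions, at SCR and SHR, was called, and 1 of 2 shoot marker regions was higher, TMM with 0.73, in the authors' deposited table.

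Rises and falls followed the level of acetylation. With the regions divided into 10 equal groups by their level in water, the median log2 fold of the lowest group was 0.71, with 635 regions higher and 21 lower. In the highest group it was -0.46, with 3 higher and 516 lower, by the folds and FDR of the authors' deposited table. The median fold over all regions was near 0 by normalisation, so a gain shared by all regions would not be seen. The difference between libraries a and b correlated with that of water at -0.0475 for TSA, against 0.184 to 0.278 for the other groups of 3 h. The TSA libraries were close in depth (2261175 and 2311352 reads), so their order may mean little. A difference in handling between TSA and water libraries was not tested. limma on the recovered reads called 2864 regions with TSA (1368 higher, 1496 lower), of which 2334 were also called in the same direction in the authors' deposited table. Without TSA library a it called 892 regions and without library b 945, 1169 without the trend, and with medians set equal 1176 higher and 1831 lower.

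**Figure D2:**
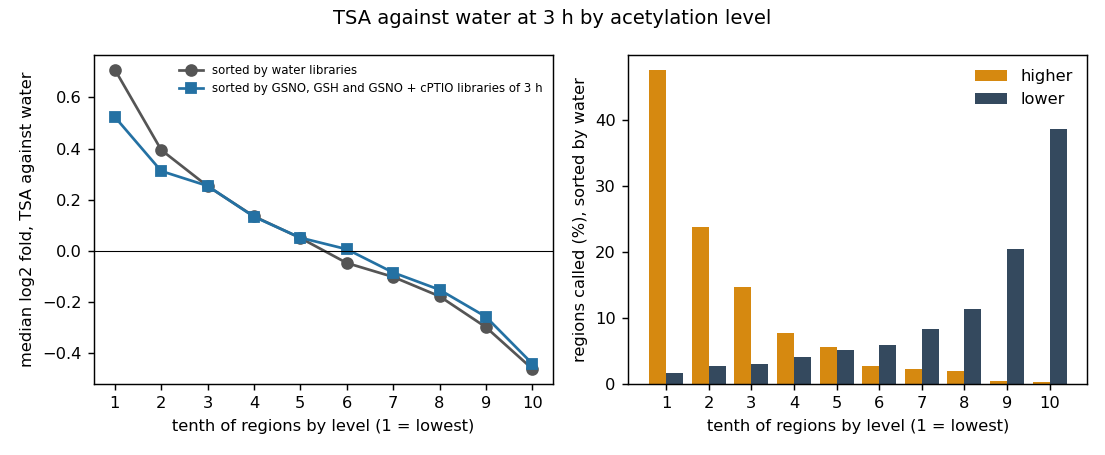
TSA against water at 3 h by level of acetylation, from the authors' deposited table. The left panel gives the median log2 fold (y axis) in 10 equal groups of regions (x axis, 1 = lowest level), sorted by the water libraries (circles) or by the GSNO, GSH and GSNO with cPTIO libraries of 3 h (squares); it falls from 0.71 to -0.46 with the first sorting. The right panel gives the percent of regions in each group called higher or lower, from 47.5% higher in the lowest to 38.6% lower in the highest.

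With GSNO for 3 h few regions were called higher, 3 of them at antenna genes. Higher were 6 regions and lower 0 in the authors' deposited table, LHB1B2 (4.51), LHCA1 (4.17), LHCB3 (3.15), MRE11 (5.04), AT5G06980 (4.76) and PRR9 (3.51). LHCA1 had 39 and 103 reads with GSNO against 1 and 7 in water, LHCB3 44 and 65 against 8 and 1, and LHB1B2 12 and 50 against 1 and 1, at least 7.58-fold higher against 3 reads per water library. At MRE11, AT5G06980 and PRR9, GSNO library a had 1 read and library b 111, 91 and 37, so these rises, at least 11.0-fold, 9.03-fold and 3.81-fold, rest on 1 library. Those 3 are named because so few regions were called. In the photosynthesis list 2 of 25 regions were higher and in the clock list 1 of 17 in the authors' deposited table, and 2 and 2 adjusted over the list alone. The other lists had 0 called in the authors' deposited table and 0 adjusted over the list alone. The authors' deposited table had 296 regions at an unadjusted p under 0.05, and limma called 0, with 393 at an unadjusted p under 0.05. The counts of 296 and 393 lie under 5% of the 13362 regions, as do those given below for GSH and for GSNO with cPTIO against water at 3 h. Without GSNO library b limma called 20, and without water library b 1.

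With GSH for 3 h, 5 of the 6 regions called with GSNO were also called higher, all but PRR9 (3.02 at an FDR of 0.106, with 1 and 23 reads, in the authors' deposited table). So were 9 others, with 14 higher and 0 lower in the authors' deposited table. The folds in the authors' deposited table were 5.31 at MRE11, 4.65 at LHB1B2, 4.57 at AT5G06980, 4.06 at LHCA1, 3.07 at PIF4, 2.51 at LHCB3, 2.39 at AT3G53830 and 2.19 at STO. AT4G21880 (1.57), SDR1, a short-chain dehydrogenase (1.49), COR413-PM1, a cold-regulated membrane protein (1.22), WRI4 (1.13), PSAD-2 (1.11), a photosystem I subunit, and AT3G15460 followed in the authors' deposited table. Against 3 reads per water library MRE11 was at least 13.2-fold, LHB1B2 at least 8.37-fold and AT5G06980 at least 7.91-fold higher. LHCA1 had 56 and 83 reads with GSH against 1 and 7, and COR413-PM1 143 and 191 against 42 and 77. The photosynthesis list had 2 of 25 higher and the clock list 1 of 17 in the authors' deposited table, and 3 and 4 adjusted over the list alone, where abscisic acid, cold and drought had 1 higher and 2 lower. Independent lists of these sizes would share 0.00629 regions, but comparisons with the same water libraries share their chance values. In 100 simulations of unchanged groups with the same water libraries, as many regions with the largest folds shared a median of 1 and at most 4. All 6 regions of GSNO and all 14 of GSH were also higher in the authors' deposited table of TSA, where the simulated groups shared medians of 5 and 11 and at most 6 and 14. The log2 folds of GSNO and GSH, across 13362 regions that are not independent replicates, correlated with Pearson's r = 0.659 (rho = 0.565), against a median of 0.509 in 100 simulations of unchanged groups with the same water libraries. Their covariance was 0.0460, against 0.0253 in the simulations, and part or all of the excess may come from the shared controls. The covariances of the other 5 pairs of treatments at 3 h, 0.0369 to 0.0744, also lay above their simulated values, of which the highest was 0.0266. These simulations count the difference that libraries a and b share between groups as noise of each library. With that part drawn in common, the simulated covariance of GSNO and GSH was 0.0163 (at most 0.0172) and r 0.513, and the groups shared at most 6 and 13 regions with TSA. Of the other pairs, GSNO and GSNO with cPTIO stood at r = 0.499 (at most 0.517 simulated), GSH and GSNO with cPTIO at 0.502 (median 0.508), and GSNO and TSA at 0.417 (median 0.499), while GSH and TSA had 0.530 (median 0.507) and GSNO with cPTIO and TSA 0.244 (median 0.498). limma called 0 regions with GSH at 3 h, with 512 at an unadjusted p under 0.05, against 542 in the authors' deposited table. Without water library b it called 492, without water library a 3, and without the trend 2.

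LHCA1 and LHB1B2 were also called higher with GSNO and cPTIO for 3 h in the authors' deposited table. LHCA1 had 50 and 58 reads with GSNO and cPTIO, with a fold of 4.07 in the authors' deposited table, and LHB1B2 had 16 and 16, at least 5.33-fold higher against 3 reads per water library. AMY3, a plastid amylase of starch breakdown, PHT4;1, a phosphate transporter of the thylakoid, and CDF3, a DOF-type factor of daily timing, were lower at -4.53, -4.28 and -2.44 in the authors' deposited table. AMY3 had 1 and 1 reads against 7 and 52 in water, at least 7.68-fold lower, and PHT4;1 1 and 1 against 8 and 40, at least 6.47-fold lower, against 3 reads per treated library. The nitric oxide, nitrate and glutathione list had a median limma fold of 0.13, with camera adjusted p = 0.0482 for a rise and adjusted p = 0.949 with an estimated correlation, and 0 of its 17 regions were called in the authors' deposited table. Photosynthesis had 1 of 25 higher in the authors' deposited table (3 adjusted over the list alone), and adjusted over the list alone circadian clock and light had 1 higher and oxidative stress, detoxification and heat shock 1 lower. limma called 0 regions, with 501 at an unadjusted p under 0.05, against 446 in the authors' deposited table. Without GSNO with cPTIO library b it called 11, without water library b 5, and 7 with the depth order of the libraries (shallower or deeper of each pair) as a block.

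**Figure D3:**
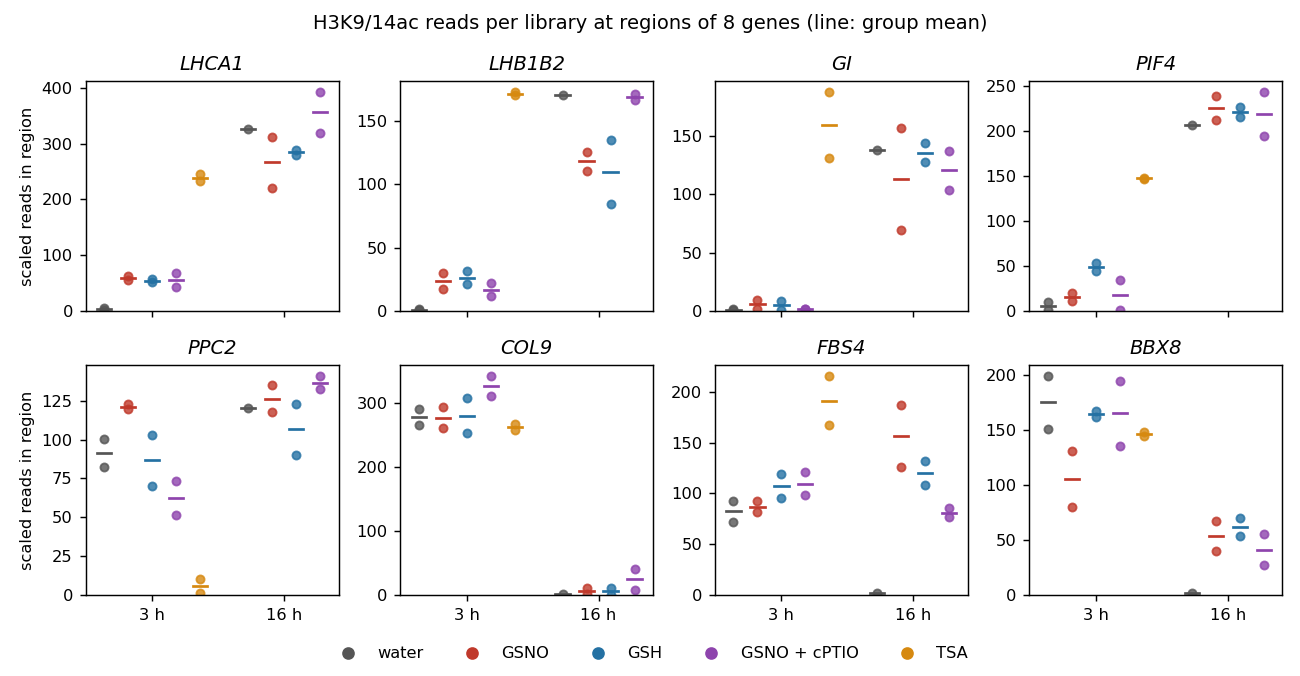
Scaled H3K9/14ac reads (y axes) at the regions of 8 genes in each recovered library (points), by treatment (colour) and time (x axis), with the group mean as a line; water at 16 h is 1 library. LHCA1 has 3.27 ± 2.73 scaled reads in water (SD, n = 2), 239 ± 9.15 with TSA at 3 h (SD, n = 2) and 326 in the water library of 16 h, in which FBS4 and BBX8 have 1.58 each.

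Direct comparison of GSNO with GSH, at the same dose and time, found 0 regions by limma at 3 h, with 220 at an unadjusted p under 0.05, and 0 without the trend. The regions with the smallest p, none past the threshold, were at AT5G56220 (-0.61 ± 0.17, log2 GSNO over GSH with SE), BBX32 (0.81 ± 0.24), DHS2 (0.54 ± 0.17), AT5G03355 (-0.61 ± 0.19) and ADT2 (0.62 ± 0.20), each at adjusted p = 1.00. For 89.3% of regions the 95% interval of the difference lay within 1 on the log2 scale, each interval taken alone and unadjusted. The intervals used a normal quantile and are narrower than the t distribution of limma's test would give. This share and those below for the other direct comparisons, also at 16 h, are thus somewhat too high. Without GSNO library b limma called 53 regions. GSNO against GSNO with cPTIO at 3 h gave 0 regions, 0 without the trend and 410 at an unadjusted p under 0.05, among them AT5G59080, AT1G01540 (0.68 ± 0.19), the sulfiredoxin gene SRX (0.82 ± 0.23) and TBL10 (0.82 ± 0.23), all at adjusted p = 1.00 in limma. The interval lay within 1 for 82.0% of regions. Without GSNO library b or GSNO with cPTIO library b it called 15. The nitric oxide, nitrate and glutathione list had a median of -0.22 in GSNO against GSNO with cPTIO, with camera adjusted p = 0.0494 and adjusted p = 0.949 with an estimated correlation.

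After 16 h, FBS4, an F-box gene of stress responses, AT1G14130, AT4G27270, AT1G07930, which encodes the elongation factor EF1-alpha, and BBX8, a B-box gene, were higher with each of GSNO, GSH and GSNO with cPTIO. At FBS4 the log2 folds in the authors' deposited table were 6.63 with GSNO, 6.25 with GSH and 5.68 with GSNO and cPTIO. The FBS4 region (AT4G35930; chromosome 4, 17019115 to 17019938) had 132 and 186 reads with GSNO and 1 read in the water library, at least 33.0-fold higher against 3 reads. That single library is the control of each comparison at 16 h, and no spread of water can be had. Of 301 regions higher in any table of 16 h, the water library of 16 h had the lowest scaled reads of all 17 libraries at 222 (73.8%, against 8.26% of all regions), a share that calling regions against this same library favours. The tables of 16 h called 45 regions higher in common, and GSNO and GSH shared 105. Independent lists would share 2.55, and as many regions with the largest folds in simulated unchanged groups with the same water library shared a median of 68 and at most 85. With the difference that libraries a and b share between groups drawn in common, the median was 73 and the highest 86. Both simulations gave the lone water library the spread of the treated pairs. If that library was noisier, more regions would be shared, so these values cannot show sharing beyond the control.

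With GSNO for 16 h, 122 regions were higher and 3 lower in the authors' deposited table. Beside FBS4, the folds in the authors' deposited table were 6.18 at AT1G14130, 5.82 at AT4G27270, 5.73 at AT1G07930, 5.50 at AT2G34730, 5.45 at AT2G39280, 5.33 at CYP81H1, a cytochrome P450, 5.07 at BBX8 and 5.05 at AT2G15830. Against 3 reads in the water library, which had 1 read at these regions and 2 at CYP81H1, the bounds ran from at least 11.0-fold (AT2G15830) to at least 24.2-fold higher (AT1G14130). A region of chromosome 3 without a linked gene, 17911969 to 17912686, had a fold of 5.72 in the authors' deposited table. Lower were AT2G45540 (-1.50), the purple acid phosphatase gene PAP12 (-1.27) and ATGRIP, a Golgi protein (-1.20) in the authors' deposited table. List members called higher were ELF3, a clock gene (1.82), WRKY6 (1.60) and RBCS2B, a small subunit of Rubisco (1.40), in the authors' deposited table, 1 in each of their lists; adjusted over the list alone, circadian clock and light had 2 and abscisic acid, cold and drought 1 higher. limma called 18 regions, 17 of them also in the authors' deposited table; in simulated reads 9.84% of the calls of this test were false. Without either GSNO library it called 7, and 34 without the trend.

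With GSH for 16 h, 279 regions were higher and 9 lower in the authors' deposited table. The largest folds in the authors' deposited table were 6.32 at the chromosome 3 region without a linked gene, 6.25 at FBS4, 6.07 at AT4G27270, 5.85 at AT1G14130, 5.79 at AT2G39280, 5.69 at AT2G34730 and AT1G07930, 5.29 at BBX8 and 5.24 at CYP81H1. A region of chromosome 4 without a linked gene, 12474763 to 12475387, had 5.37 in the authors' deposited table. Against 3 reads the bounds ran from at least 13.1-fold (BBX8) to at least 26.6-fold higher (the chromosome 3 region), CYP81H1 apart. CBF3, a transcription factor of cold tolerance, fell by 1.38 ± 0.32 on the log2 scale (SE; limma adjusted p = 0.00413), where SE and p, as in all limma values of 16 h against water, take the 1 water library to vary like the treated ones. The other lower regions in the authors' deposited table were AT3G17365 (-1.19), CYP705A15 (-1.14), AT1G04770 (-1.08), AT1G02080 (-1.07), OCT5 (-1.04), AT3G24780 (-1.01), AIP3 (-0.95) and AT3G07690 (-0.89). ABF4, a factor of abscisic acid signalling, rose by 1.85 ± 0.33 in limma (SE; adjusted p = 4.91e-05), and ELF3 and RBCS2B had folds of 1.66 and 1.31 in the authors' deposited table. Abscisic acid, cold and drought had 1 higher and 1 lower of 17 regions, and circadian clock and light 1 higher of 17, in the authors' deposited table (1 and 2, and 2 and 1, adjusted over the list alone). limma called 313 regions (262 higher, 51 lower), 192 of them in the same direction in the authors' deposited table, and in simulated reads 13.3% of the calls of this test were false. Without either GSH library it called 0, with 1988 at an unadjusted p under 0.05 in the full fit, and with the spread shared over all groups of 16 h it called 12. The folds of GSNO and GSH at 16 h correlated across regions with r = 0.858 (rho = 0.776), against 0.707 in simulated unchanged groups with the same water library, with a covariance of 0.169 against 0.0606. With the difference of libraries a and b drawn in common, the simulated r was 0.734 and the covariance 0.0553. GSNO with cPTIO had covariances of 0.159 with GSNO and 0.158 with GSH, against 0.0604 and 0.0605 in the first simulations. The excess was thus not particular to GSNO and GSH. All these simulations gave the lone water library the spread of the treated pairs, so they cannot tell the excess from noise of that library.

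With GSNO and cPTIO for 16 h, 61 regions were higher and 14 lower in the authors' deposited table. Folds there were 6.14 at AT1G14130, 6.02 at AT1G07930, 5.89 at AT4G27270, 5.61 at AT2G34730, 5.12 at AT2G15830, 5.03 at CYP81H1 and 4.71 at BBX8 in the authors' deposited table. Against 3 reads the bounds ran from at least 8.72-fold (BBX8) to at least 23.4-fold higher (AT1G14130), CYP81H1 apart. Losses were largest at WLIM2a, an actin-binding LIM protein (-5.96), and at JMJD5, a histone demethylase tied to the clock (-3.79), in the authors' deposited table. WLIM2a had 1 and 1 reads against 54 in water, at least 20.8-fold lower, and JMJD5 1 and 1 against 12, at least 4.62-fold lower. AT2G01630 (-3.36), AT1G64330 (-2.85), TBL24 (-2.27), TMN6 (-2.11), AT3G56270 (-2.08), AT5G48470 (-2.07), MRB1 (-2.03) and LpxB (-1.90) were also lower in the authors' deposited table. The photosynthesis list had a median limma fold of 0.26 with camera adjusted p = 0.00552 for a rise, adjusted p = 0.949 with an estimated correlation, and 0 of 25 regions called in the authors' deposited table. Of the 12 lists 0 had a called region there, and adjusted over the list alone abscisic acid, cold and drought had 1 higher. limma called 0 regions with 664 at an unadjusted p under 0.05, against 785 in the authors' deposited table. Without GSNO with cPTIO library b it called 273, without library a 47, and 13 with the spread shared over all groups of 16 h.

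**Figure D4:**
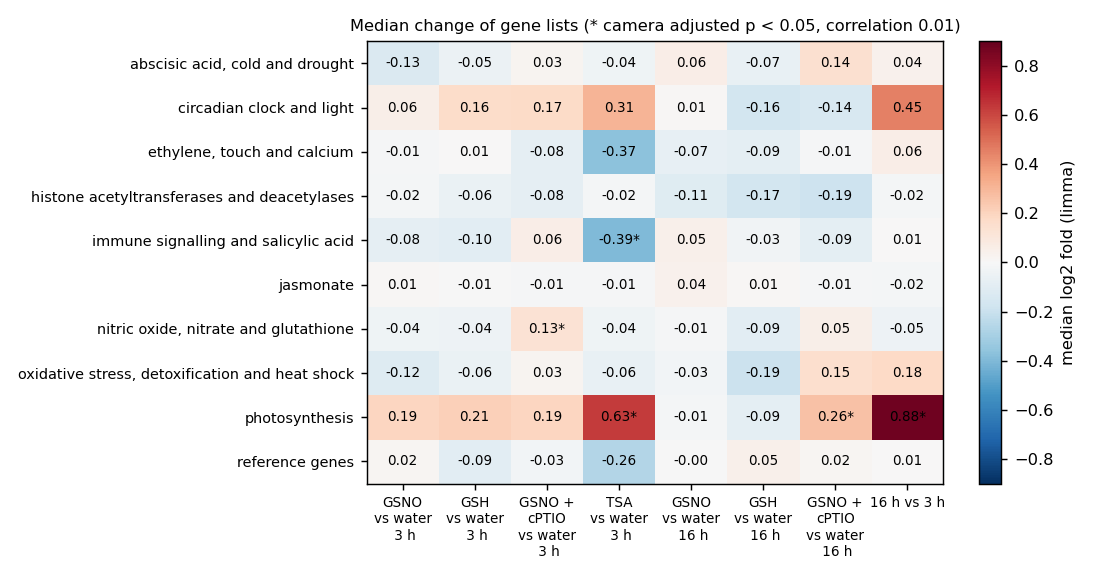
Median log2 fold from limma (colour and number) of 10 gene lists (y axis) in each treatment against water and in 16 h against 3 h (x axis). An asterisk marks camera adjusted p under 0.05 at a correlation of 0.01; photosynthesis has the largest medians, 0.63 with TSA and 0.88 at 16 h against 3 h, and no marked cell stays under 0.05 with an estimated correlation.

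Between GSNO and GSH at 16 h limma called 0 regions, 23 with the depth order of the libraries as a block, 0 without the trend and 452 at an unadjusted p under 0.05. The smallest p were at AT1G24140 (0.69 ± 0.16), KUF1 (0.67 ± 0.17), AT2G34620 (-0.65 ± 0.18), GSTU24, a glutathione transferase (1.22 ± 0.33), and MIZ1 (0.79 ± 0.22), as log2 GSNO over GSH with SE, each at adjusted p = 0.999. The 95% interval lay within 1 on the log2 scale for 91.2% of regions. Without GSNO library b limma called 378. GSNO against GSNO with cPTIO gave 0 regions, 49 with the depth order as a block, 0 without the trend and 764 at an unadjusted p under 0.05, led by LZF1, a B-box gene of light signalling (1.31 ± 0.23, SE; adjusted p = 0.437), ATGRIP (-1.07 ± 0.22), LBD41 (-0.89 ± 0.19), MCCA (-0.76 ± 0.18) and AT2G16710 (-0.91 ± 0.23), the latter at adjusted p = 0.849 in limma. The interval lay within 1 for 76.7% of regions. Without GSNO with cPTIO library b it called 321, without its library a 17 and without GSNO library b 2. Photosynthesis genes had a median of -0.28 in this comparison, with camera adjusted p = 7.46e-05 for a fall and adjusted p = 0.949 with an estimated correlation.

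With the 1 water library of 16 h taken to vary like the other groups, limma called a difference in response between 3 h and 16 h at ACA8, a calcium pump of the plasma membrane, and ETR2, an ethylene receptor, with GSNO, and at 16 regions with GSH, among them ACA8, BBX8 and FBS4. ACA8 had 71 and 210 reads with GSNO, 76 and 136 with GSH, and 6 in the water library of 16 h, and 212 and 327 in the water libraries of 3 h. The fitted difference with GSNO was 3.59 ± 0.44 at ACA8 (log2 with SE; limma adjusted p = 0.000293) and 1.77 ± 0.31 at ETR2 (adjusted p = 0.0385), which rests on that 1 library. With GSH it was 2.95 ± 0.42 at ACA8 (adjusted p = 0.00146) in limma, and BBX8 and FBS4 had adjusted p = 0.00439 and 0.0135. For GSNO with cPTIO limma called 0 regions, with 598 at an unadjusted p under 0.05 and 6 called without the trend; ETR2 had 1.97 ± 0.31 at adjusted p = 0.0605. The GSH count was 0 without GSH library a of 3 h and 235 without water library b of 3 h.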

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

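Of the tests in this part, those of a treated library in the place of water, of loss in water-treated seedlings, of folds that share no water library and of a difference of libraries a and b drawn in common were chosen after the results were seen, and the others before.

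A limma test of the difference in response to GSNO between 3 h and 16 h, with 1 water library at 16 h, called 2 regions, ACA8 and ETR2, with 620 at an unadjusted p under 0.05. The count was 1 without water library a of 3 h, 5 without water library b and 6 without GSNO library b of 16 h. For GSH the same test called 16 regions, led in p by ACA8 and AT1G61150 (3.98 ± 0.57, log2 with SE; limma adjusted p = 0.00146). That count was 0 and 1 without GSH libraries a and b of 3 h, 5 and 2 without those of 16 h, and 77 and 235 without water libraries a and b of 3 h. TSA libraries of 3 h had a mean of 29.5 peaks on the plastid genome, above the water mean of 17.5, in data outside the 13362 regions. The TSA libraries, replicates 1 and 2, had 31 and 28 such peaks and the water libraries 10 and 25. GSNO had 3 and 26, GSH 8 and 31, and GSNO with cPTIO 5 and 31. The gap thus lies in replicate 1, which was low in each group of 3 h but TSA, and the difference was not tested.

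Regions such as FBS4, BBX8 and AT1G07930 were higher with each treatment at 16 h against 1 water library. With GSH, limma called 262 regions higher against water, 889 and 97 against libraries a and b of GSNO with cPTIO as the single control, and 240 and 0 against those of GSNO. Libraries of 1 group thus gave counts far apart, and noise of a single control library may account for a count of this size, though these controls also carry another treatment and not each gave such a count. The design gives a biological alternative, loss of acetylation in water-treated seedlings by 16 h, which the low reads of this library cannot test, since the regions were called against it. The peak list of water replicate 2 at 16 h could have decided, but it had a peak at 0% of these regions and at 0.142% of all regions, so loss in water cannot be told apart from the state of that library.

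With TSA at 3 h weakly acetylated regions, LHB1B2, GI and PRR9 among them, were higher and strongly acetylated ones lower. Sorting by water libraries that also enter the fold would give such a trend by regression to the mean. Sorted by other libraries of 3 h, the difference in median log2 fold between the lowest and highest of 10 groups was 0.97 (95% interval over regions 0.93 to 1.02). Sorted on water it was 1.17. The interval leaves out the spread between libraries. A weak region that entered the common set through a peak with TSA would look higher under either sorting, which this test cannot exclude. An even background of reads in the TSA libraries would also raise weak regions. Of 1425 rises, 1165 (81.8%) were larger than a background of 87.6 reads per kb allows, which argues against it as the cause of those. A spread of acetylation over weak sites when deacetylases are blocked stays a hypothesis that was not tested, and with a median fold normalised to near 0 a shift of all regions would not be seen.

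At 3 h regions at LHB1B2, LHCA1, LHCB3, MRE11 and AT5G06980 were called higher with GSNO and with GSH in the authors' deposited table. With GSNO the rises at MRE11 and AT5G06980 rest on library b. limma called 0 regions with GSNO and 0 with GSH. The covariance of their log2 folds was 0.0460, above the highest of 100 simulated unchanged groups sharing their water libraries, 0.0269 or, with the difference that libraries a and b share between groups drawn in common, 0.0172. Folds that share no water library, each library set against the water library of its depth order, had a covariance of 0.0109 (95% interval over regions 0.00629 to 0.0159), but the 2 pairings behind it gave 0.00177 and 0.0201 and all 8 pairings -0.0555 to 0.0258, so chance values of the shared water libraries cannot be told apart as the source. The 8 pairings that do share a water library had a mean of 0.103. If treated seedlings stood at a later point of the daily cycle, regions that rise with time would be higher: 200 that rose most in the GSNO with cPTIO libraries had a median log2 fold of 0.12 with GSH and 0.08 with GSNO, and 200 that fell most -0.00 and 0.01, on both sides of the bounds set beforehand, which keeps that explanation open. With TSA at 3 h the same sets of regions had medians of 0.34 and -0.16. For TSA, a later point of the daily cycle therefore cannot be told apart from an effect of the inhibitor. A response to the glutathione part that GSNO and GSH have in common was not tested.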

How the results depend on the processing

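The limma test on recovered reads for treatment against water, fry, the spread shared over groups, the depth order as a block, single-gene regions and the comparison of 16 h with 3 h were chosen after the data were seen. Of the alternatives chosen before that, 69 kept a count or value within its bounds and 46 did not, and of those added later 81 did and 30 did not. TSA at 3 h (2778 regions in the authors' deposited table) stayed between 2777 and 3765 with other thresholds, a filter or limma. With regions of a mean of at least 20, 2 were called for GSNO and 2 for GSNO with cPTIO at 3 h, which follows from leaving out regions, and at adjusted p under 0.1 GSNO with cPTIO had 9. limma on recovered reads called 0 for GSNO, 0 for GSH and 0 for GSNO with cPTIO at 3 h, 18 for GSNO at 16 h and 0 for GSNO with cPTIO at 16 h. The cause was not tested. limma without trend called 2 (GSH, 3 h), 1169 (TSA, 3 h) and 34 (GSNO, 16 h). At adjusted p under 0.1 it called 511 for GSH at 16 h, and with the spread over all groups of the time 12 for GSH and 13 for GSNO with cPTIO at 16 h. Leave-one-out fits against water, in which a lone library is assumed to vary like the other groups, called 0 to 20 (GSNO, 3 h), 0 to 492 (GSH, 3 h), 0 to 11 (GSNO with cPTIO, 3 h), 892 to 3800 (TSA, 3 h), 7 to 7 (GSNO, 16 h), 0 to 0 (GSH, 16 h) and 47 to 273 (GSNO with cPTIO, 16 h). For GSNO against GSH leave-one-out fits called 0 to 53 at 3 h and 0 to 378 at 16 h, and for GSNO against GSNO with cPTIO 0 to 15 and 0 to 321. For responses that differ by time, limma without trend called 18 (GSNO), 35 (GSH) and 6 (GSNO with cPTIO), adjusted p under 0.1 gave 5, 31 and 7, the spread over all groups gave 16 for GSNO and 24 for GSNO with cPTIO, and medians of libraries set equal gave 3 for GSNO with cPTIO. Their leave-one-out ranges were 1 to 6 (GSNO), 0 to 235 (GSH) and 0 to 27 (GSNO with cPTIO, 6 without its library a and 27 without b of 16 h). The cause was not tested. The 7 gene list calls became 0 with the correlation estimated, 5 with fry and 7 with regions overlapping 1 gene only. The correlations of GSNO and GSH over the regions above the median level were 0.591 at 3 h and 0.791 at 16 h. Peaks of at least the median width gave means of 4332.5 (water), 5551.5 (GSNO), 6451.5 (GSH), 4843 (GSNO with cPTIO) and 8675 (TSA) at 3 h, and 4881 (GSNO), 5813.5 (GSH), 5490 (GSNO with cPTIO) and 2294 (TSA) at 16 h, and an overlap of replicates of 46.4%, since fewer peaks are counted. Genes with a peak in at least 1 replicate numbered 13312 (water), 13132 (GSNO) and 13182 (GSNO with cPTIO) at 3 h, and 7232 (water), 12934 (GSNO), 10590 (GSNO with cPTIO) and 13311 (TSA) at 16 h. Within 500 bp of a gene end lay 55.5% of regions. No paired analysis was possible because the recovered libraries carry no replicate number, in so far as pairing goes by the labels' numbers, and depth order was tried in their place. The shallower and the deeper libraries of a pair deviated together between groups, with correlations of 0.0822 to 0.326 for pairs of groups without TSA and -0.0687 to 0.0337 with TSA. With this depth order as a block limma called 7 regions for GSNO with cPTIO at 3 h, 23 for GSNO against GSH and 49 for GSNO against GSNO with cPTIO at 16 h; it moved no other count by over 1.5 times among the fits that could take it, those without the lone water library as a control. Depth order is no replicate number, and the cause was not tested. Not run either were other pseudocounts, scaling, trend and leave-one-out for the authors' deposited FDR itself, and windows on gene starts, which need a strand. Fits of 16 h without the water library were not run where it is the whole control. Depth limits regions at 1 read in a library, whose log2 folds depend on that floor.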

Other observations

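The comparison of 16 h with 3 h, the splits of its libraries and the test of TSA against time were chosen after the data were seen, as all in this part.

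Between 3 h and 16 h of culture, acetylation differed at some regions of clock and antenna genes, those of clock genes in both directions. Over water, GSNO, GSH and GSNO with cPTIO, 8 libraries of 3 h and 7 of 16 h, regions were higher at 16 h at AT5G06980, PRR9 and PIF4, and at LHCB3, and lower at COL9, a CONSTANS-like gene, COR27, a gene regulated by cold and the clock, and JMJD5. AT5G06980 went from 15.7 ± 19.8 scaled reads (SD, n = 8) to 500 ± 24.6 (SD, n = 7), and COL9 from 290 ± 29.8 to 10.9 ± 14.0. limma called 848 regions higher and 647 lower, 1495 in all, with treatment in the model. In 261 of the higher and 160 of the lower regions no library of 1 time overlapped those of the other, which chance gives for 0.0155% of regions per direction. The other largest rises were at MRE11 (5.24), DOG1, a regulator of seed dormancy (4.93), AT3G53830 (4.32), the kinase gene CIPK20 (4.29), BBX16 (3.92) and CDF3 (3.83), as log2 folds in limma, and the other largest falls at AT4G33980 (-5.76), AT1G17665 (-3.88), CENP-C, a centromere protein (-3.16), AT1G11210 (-2.46), BBX8 (-2.31), ACA8 (-2.21) and TAG1, an enzyme of oil synthesis (-2.11). BBX8 had 1 read and ACA8 6 reads in the lone water library of 16 h. Time and sampling at another hour of the day are the same contrast here.

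Photosynthesis had 18 higher and 1 lower of 25 regions (as many adjusted over the list alone), with LHCA4 at 2.26 ± 0.19, LHCA3 at 1.76 ± 0.15, LHCB5 at 1.63 ± 0.14 and LHCB6 at 1.58 ± 0.13 (log2 with SE). Camera gave adjusted p = 2.85e-17 for this list, adjusted p = 0.0576 with an estimated correlation. It did not call the list of circadian clock and light, whose regions went both ways. Circadian clock and light had 6 higher and 3 lower of 17 regions (8 and 5 adjusted over the list alone), among them PIF5 (0.76 ± 0.08) and the clock gene BOA, lower at 88.1 ± 46.5 scaled reads (SD, n = 7) against 333 ± 27.3 (SD, n = 8). Oxidative stress, detoxification and heat shock had 3 higher and 1 lower of 17 (5 and 2 adjusted over the list alone), CAT2, CAT3 and FSD1 among the higher and HSP101 lower. At 3 h FSD1 had 1 to 6 reads in the shallower and 169 to 255 in the deeper library of the 4 groups, so its rise rests on the shallower ones. NIA2, a nitrate reductase gene, fell by 0.79 ± 0.14 and GR1, a glutathione reductase gene, by 0.51 ± 0.16, 2 of 17 in their list with 0 higher. Immune signalling had 3 higher and 2 lower of 32, jasmonate 0 and 2 of 21, abscisic acid, cold and drought 2 and 1 of 17 (4 and 1 adjusted over the list alone), ethylene, touch and calcium 1 and 0 of 15 (0 adjusted over the list alone), and histone acetyltransferases and deacetylases 1 and 2 of 22. Reference genes had 0 of 14 called by limma, GAPC2 with the smallest adjusted p of 0.0615, and SCR was 1 of 2 root marker regions called higher. Among 100 splits of the 15 libraries without a treatment term, 1, the real one, called as many regions (1463, against 26 in the highest other). A chance split is thus an unlikely source of the count. The splits take all libraries as exchangeable, and 100 of them cannot show a share smaller than 1 in 100.

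The regions higher with TSA include several that rose with time, such as AT5G06980, PRR9, PIF4 and LHCB3. Of 633 regions higher at 16 h in a fit without water libraries, 156 were also higher with TSA at 3 h, where independent lists would share 67.5, and 52 were lower, where they would share 64.1. Of 429 regions lower at 16 h, 11 were higher with TSA, against 45.8 for independent lists, and 57 lower, against 43.4. Since weak regions rose with TSA, the median TSA fold of regions higher at 16 h was set against regions of the same level. This left 0.15 (95% interval over regions 0.11 to 0.20, without the spread between libraries). For regions lower at 16 h the same difference was -0.05, without an interval. For rises these values go with the hypothesis that TSA moves regions the way they move from 3 h to 16 h. For falls the difference at the same level was small and decides nothing. The hypothesis was found and tested on the same data.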
